A study of Methylosinus trichosporium with 12 samples.

How the data were processed

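Total RNA was taken from mid-exponential cultures of Methylosinus trichosporium OB3b grown on methane in a nitrate mineral salts medium at 30 °C, depleted of rRNA and sequenced, per the labels. Groups were taken from the labels: 0 or 10 µM copper by 0 or 25 µM cerium, with 3 libraries each and 12 in all. The labels call the libraries of a condition biological triplicates. They name no culture batch or date, so a batch shared by the cultures of 1 condition is confounded with that condition.

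The submitters' processing notes list BWA, FastQC 0.11.5, SAMtools 1.3.1, HTSeq 0.6.1p1 and DESeq2 1.12.4. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Per the file headers, each of the authors' 6 tables, 1 for each pair of conditions, holds DESeq2 output for the same 4912 features. The mean normalized count (baseMean) is a signal averaged over all 12 libraries by the authors. It is identical in all 6 tables, so they come from 1 normalization. The log2 fold change and its standard error are the authors' deposited values on the log2 scale. The Wald statistic, a score with no fixed range, is in the authors' deposited tables the fold change over its standard error. The p-value and the adjusted p-value are the authors' deposited values, and an adjusted p-value left blank by DESeq2 stayed blank. Blank adjusted values beside a p-value occurred for 95 features of low count in the copper comparison without cerium and for 475 in the cerium comparison with copper, and the lowest mean normalized count with an adjusted p was 11.8 and 56.6 there. The 27 features without a p-value were 12 without counts and 15 with counts. Whether the authors shrank the fold changes is not given in the sources used here, and shrinkage would understate the changes of features with low counts.

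The headers do not say which condition is the numerator. Fold changes added up across the 6 tables to within 1e-08, which fixes their relative signs and is what 1 fit of all 12 libraries gives. The overall sign was then taken from the standard errors, since at equal dispersion the condition with the higher count adds less variance to a log fold change. Of 5300 fold changes above 1 in size, 4792 (90.4%) went with the orientation used, between 81.1% and 100% by table. In simulated data this check matched 100% of features. That simulation used 1 constant dispersion and no sampling noise, so its outcome was fixed and adds no support for the sign. All log2 fold changes are printed as the condition with the metal over the condition without it, and as copper alone over cerium alone. Printed standard errors are those of the authors' fit.

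The test of each comparison was the authors' adjusted p at a threshold of 0.05, with no new fit. The difference of the pair of cerium effects was tested for each feature by a two-sided z test, the difference over the root of the summed squared standard errors, with Benjamini-Hochberg adjustment over 4885 features. In simulated data with this step's standard errors, 30% of differences of 1 and 87% of differences of 2 on the log2 scale were recovered, and 5.65% of calls were unchanged features. The simulated noise had the size of the deposited standard errors. The real cerium effects without copper spread less, with a median absolute log2 fold change of 0.138 at a median standard error of 0.296. These shares therefore need not carry over to the data. Overlaps used a two-sided Fisher's exact test on features with an adjusted p in both tables. Implied shares were computed from the mean normalized count and the fold changes of each feature, with equal weight to the 4 conditions, and as a percent of the summed implied counts of that condition. They carry no error of their own. Runs were defined as at least 3 features with consecutive identifier numbers, an adjusted p below 0.05 and a log2 fold change of at least 2 in 1 direction.

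Of 26 gene lists fixed before the data were examined, 25 need gene names or products and were not analysed here, among them those of the methane monooxygenases and methanol dehydrogenases. The remaining list, structural RNA, was matched by the class that identifiers carry (50 tRNA and 6 rRNA features, with 15 misc_RNA features kept apart). It was tested with cameraPR of limma 3.58.1 on the Wald statistic at a preset inter-gene correlation of 0.01. Adjustment was over the 4 single-metal comparisons. An estimated correlation needs values per library and was not used here. On simulated lists of independent normal scores without a shift, 2.4% had a p below 0.05, and all lists shifted by 1 did. The Wald statistics of the copper comparisons spread more widely than these scores, and features are not independent. The share recovered in the simulation therefore does not carry over to the real lists.

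The rule for named features, also fixed before the data were examined, took the 10 highest and the 10 lowest log2 fold changes past the threshold with a mean normalized count of at least 50 in each single-metal comparison. It took 5 and 5 in the other comparisons and the 10 smallest p-values of the test of the difference. The rule asked for a gene symbol or product, which the tables do not pair with the identifiers. The first 2 in each direction are therefore printed by identifier, without a name, and the others are summarised as ranges or runs. The runs and their follow-up tests were chosen after the values were seen.

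Alternatives were an adjusted p below 0.01, a log2 fold change of at least 1, Benjamini-Hochberg adjustment over all features with a p-value, a mean normalized count of at least 10, fold changes shifted to a median of 0, other settings of the list test, and counts without RNA features (tRNA, rRNA and misc_RNA) or without identifiers numbered from 3. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3. Precision comes from 3 libraries per condition, with a median standard error of 0.29 to 0.30 by comparison. Depth per library, the spread between libraries and outlying libraries were not analysed here, since the tables hold conditions and no libraries.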

Results

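The transcriptome of Methylosinus trichosporium OB3b, a bacterium that grows on methane, was measured by sequencing of rRNA-depleted total RNA from methane-grown cultures in 4 growth media. The media held 0 or 10 µM copper, each with 0 or 25 µM cerium, and every condition had 3 libraries that the labels call biological triplicates. Cerium is a lanthanide. As background, methane-oxidising bacteria of this kind are known to switch between forms of methane monooxygenase with copper supply, and between forms of methanol dehydrogenase with lanthanide supply. The values used are the authors' deposited tables of the 6 pairwise comparisons, which list 4912 features of the genome by identifier and do not pair the identifiers with gene names. Of these features, 4885 had a p-value in each comparison and 12 had no count. The depth of each library is unknown, since the tables hold no values per library. The mean normalized read counts of all features sum to 11771734, an average over the 12 libraries, and the 2 most abundant features held 20.1% of that sum. As counted, the 6 rRNA features held 0.158% of that sum and the 50 tRNA features 0.302%, where near-identical rRNA copies can share or lose reads.

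Copper added to cultures without cerium strongly lowered 2 runs of consecutively numbered features, 1 of them very abundant. In the authors' deposited table, 469 features were higher and 357 lower with 10 µM copper at an adjusted p below 0.05, of 4790 with an adjusted p. The lowest feature, ADVE02_v2_12510, had a log2 fold change of -9.51 (SE 0.23) in the authors' deposited table, and ADVE02_v2_12513 had -9.05 (SE 0.33, adjusted p 4.95e-158). Both belong to a run of 10 consecutively numbered features that all fell, with a median log2 fold change of -8.22 in the authors' deposited table and a largest adjusted p of 2.6e-13. These 10 features held an implied 24.5% of all normalized counts in cultures without either metal and 0.0650% in cultures with copper alone. A second run of 13 consecutively numbered features also fell, with a median of -5.16 in the authors' deposited table. The strongest rises, in the authors' deposited table, were those of ADVE02_v2_12041 (5.95, SE 0.26, adjusted p 9.91e-112) and ADVE02_v2_12040 (4.46, SE 0.34, adjusted p 2.03e-36). A run of 16 consecutively numbered features rose by a median of 2.59, between 2.32 and 2.75, in the authors' deposited table. Its implied share of all normalized counts was 0.113% without either metal and 0.801% with copper alone. Changes of at least 2 on the log2 scale were found for 41 features that rose and 59 that fell. Among the 10 highest features with a mean normalized count of at least 50, log2 fold changes in the authors' deposited table ran from 2.64 to 5.95, and among the 10 lowest from -9.51 to -5.73. The runs here and below were chosen after their values were seen, and consecutive numbers were not checked against a genome map. The balance of rises and falls turned with the processing, to 394 higher and 407 lower with the median feature shifted to 0 and to 179 higher and 197 lower at an adjusted p below 0.01. The count of called features was 376 at that threshold and 481 with an absolute log2 fold change of at least 1.

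With cerium present in both media, copper again lowered the same 2 runs and changed many more features. According to the authors' deposited table, 1488 features were higher and 1479 lower with copper, of 4885 with an adjusted p. ADVE02_v2_12510 had a log2 fold change of -10.00 (SE 0.23) and ADVE02_v2_12513 one of -9.42 (SE 0.33, adjusted p 1.54e-171) in the authors' deposited table. All 10 features of the run that holds this pair fell, as did all 13 of the other run, with medians of -8.63 and -5.41 in the authors' deposited table. The highest features were ADVE02_v2_12105 (6.58, SE 0.35, adjusted p 6.47e-76) and ADVE02_v2_12108 (6.41, SE 0.32, adjusted p 1.43e-84) in the authors' deposited table. They belong to a run of 13 consecutively numbered features that all rose with copper in cerium medium, by a median of 5.97 in the authors' deposited table. The 16 features that rose with copper without cerium rose here too, by a median of 3.72 in the authors' deposited table. A further run of 14 features rose by a median of 2.67, against 1.61 without cerium, in the authors' deposited tables. The copper effect with cerium minus that without was positive for each member, between 0.69 and 1.34 in this run and between 1.02 and 1.23 in the run of 16. By the z test described below, 0 features of these runs passed the adjusted threshold and 0 had an unadjusted p below 0.05, at median standard errors of the copper effects of 0.49 and 0.62, which leave differences of this size undecided. Changes of at least 2 on the log2 scale were found for 171 features that rose and 225 that fell. With an absolute log2 fold change of at least 1, the count was 1750 features.

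**Figure D1:**
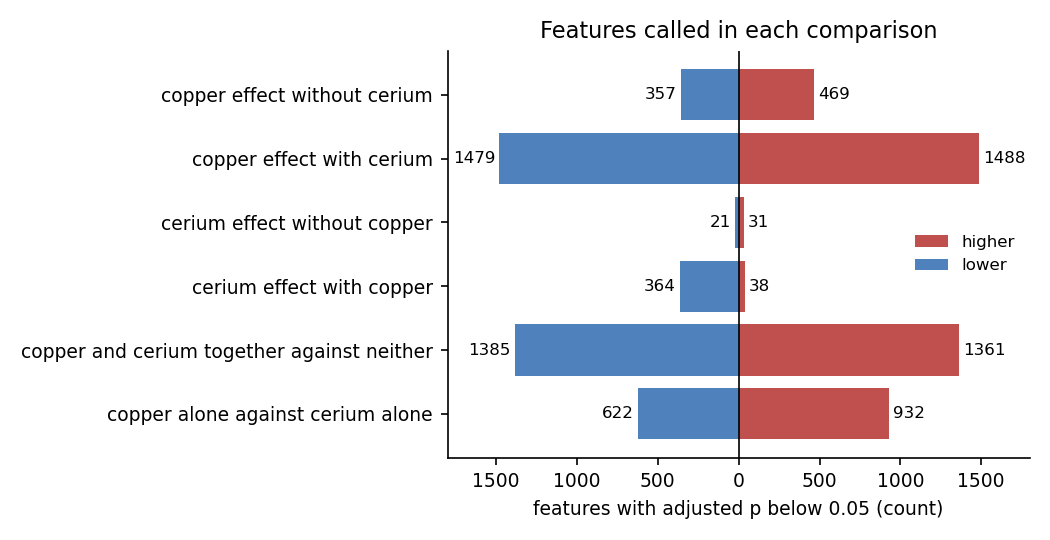
Number of features with an adjusted p below 0.05 in each of the authors' 6 pairwise comparisons, with features higher in the first-named condition to the right of 0 and features lower in it to the left. Copper was called for 826 features without cerium and 2967 with it, and cerium for 52 without copper and 402 with it.

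The copper effects without and with cerium rest on separate libraries, so their overlap needs no correction for shared controls. Their p-values appear to come from 1 fit of all 12 libraries, however, so the same features can be favoured in both lists. The counts for independent lists are therefore a reference only, and the p-values of the overlap are too small. Of the 469 features that rose without cerium, 422 also rose with it, against 145 for independent lists (odds ratio 27.6, two-sided Fisher's exact p 1.14e-176, 4790 features tested in both). Of the 357 that fell, 310 fell in both, against 109 for independent lists (odds ratio 18.7, two-sided Fisher's exact p 5.17e-118). Another 10 features were called in opposite directions. Features are not independent replicates, since neighbouring ones moved together. Across features, the median absolute log2 fold change was 0.42 without cerium and 0.76 with it, at median standard errors of 0.29 in both. Pearson's r of the pair of copper effects across features was 0.84 and Spearman's rho 0.85. For 2225 features copper was called with cerium and not without it, and 54 of these passed the test of the difference itself.

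Cerium in copper-free medium was called for few features, with large changes among them. In total 31 features were higher and 21 lower with 25 µM cerium at an adjusted p below 0.05 in the authors' deposited table, with a median absolute log2 fold change of 2.45 among them. An unadjusted p below 0.05 was found for 125 of 4885 features (2.56%), under the share that no effect at all would give. The p-values therefore look conservative here, and smaller changes can be missed. The contrast with the counts of the other comparisons may partly reflect this. The 2 lowest, ADVE02_v2_12106 (-6.24, SE 0.40, adjusted p 4.71e-52) and ADVE02_v2_12109 (-6.19, SE 0.44, adjusted p 1.34e-41) in the authors' deposited table, belong to the run of 13 features that rose with copper in cerium medium. All 13 fell, with a median log2 fold change of -5.29 and a range of -6.24 to -3.21 in the authors' deposited table. Their implied share of all normalized counts was 1.58% without either metal and 0.0243% with cerium alone. The highest features were ADVE02_v2_30032 (5.11, SE 0.45, adjusted p 1.71e-27) and ADVE02_v2_12117 (3.89, SE 0.33, adjusted p 4.46e-30) in the authors' deposited table. The implied normalized count of ADVE02_v2_30032 was only 10.6 without either metal, against 368 with cerium alone, so its fold change rests on a low count. Of the 31 features that rose, 21 had an identifier whose number starts with 3, a series of 152 features, and without that series 10 rose and 19 fell. A run of 5 of them rose by a median of 3.03 in the authors' deposited table. ADVE02_v2_12117 stands in a run of 3 features that rose by a median of 2.67 in the authors' deposited table.

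In copper-grown cells, cerium lowered far more features than it raised. The authors' deposited table holds 364 features lower and 38 higher with cerium at an adjusted p below 0.05, of 4410 with an adjusted p. The lowest was ADVE02_v2_11076, with a log2 fold change of -4.12 (SE 0.59, adjusted p 1.27e-09) in the authors' deposited table. This feature had the highest mean normalized count of all. It held an implied 14.4% of all normalized counts without either metal, 17.5% with cerium alone, 9.52% with copper alone and 0.685% with both. ADVE02_v2_14428 followed with -3.15 (SE 0.61, adjusted p 5.81e-05) in the authors' deposited table, and belongs to a run of 10 features that all fell, with a median of -2.42. A run of 8 features fell with a median of -2.19 in the authors' deposited table. The highest were ADVE02_v2_12117 (3.55, SE 0.33, adjusted p 1.56e-24) and ADVE02_v2_12118 (3.02, SE 0.26, adjusted p 1.68e-27) in the authors' deposited table. Both are in the run of 3 that rose with cerium without copper, and all 3 rose here, by a median of 3.02 in the authors' deposited table. The 13 features that fell with cerium in copper-free medium had a median of -0.28 in copper-grown cells, and 0 of the 13 were called by the authors' DESeq2 adjusted p in the authors' deposited table, with 2 at an unadjusted p below 0.05. The count of called features was 183 at an adjusted p below 0.01 and 260 with an absolute log2 fold change of at least 1.

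**Figure D2:**
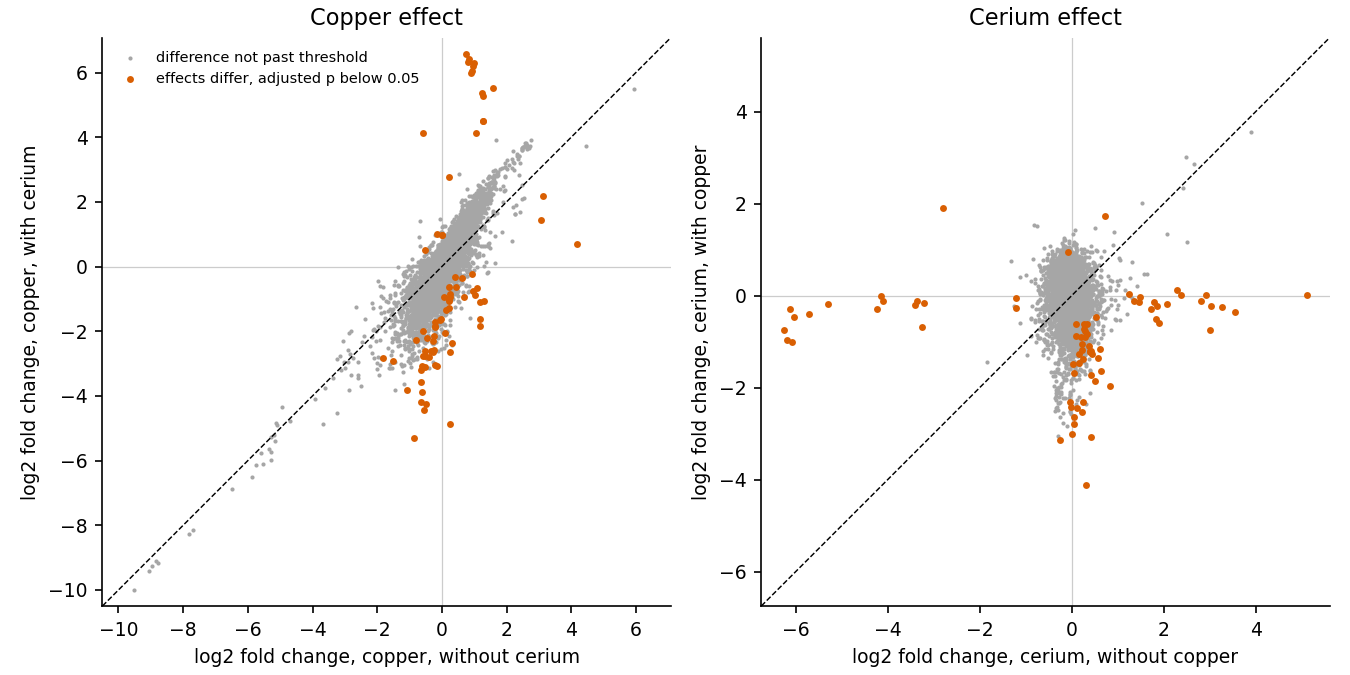
Log2 fold changes of all features with a p-value, for copper (left) without and with cerium and for cerium (right) without and with copper, with the line of equal effects dashed. The 77 features whose effects differed at an adjusted p below 0.05 are in colour, and most others scatter along a line for copper (Pearson's r 0.84 across all features) and around 0 for cerium (r 0.01).

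The calls of the pair of cerium comparisons shared 6 features that rose, against 0.259 for independent lists (odds ratio 34.0, two-sided Fisher's exact p 1.39e-07, 4410 features tested in both). Of these 6, 3 are the run that rose in both media. Neighbouring features moved together and the calls appear to come from 1 fit, so this p-value is too small. They shared 1 feature that fell, against 1.73 for independent lists (two-sided Fisher's exact p 1), and 1 feature was called in opposite directions. Pearson's r of the cerium effects across features was 0.01 and Spearman's rho -0.11.

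The cerium effects with and without copper were then compared directly, by a z test of their difference with Benjamini-Hochberg adjustment. The effects differed for 77 of 4885 features, and for 50 at an adjusted p below 0.01. An unadjusted p of the z test below 0.05 was found for 706 features (14.5%). The median standard error of the difference was 0.41, so smaller differences can be missed and the 77 need not be all. Cerium acted more positively with copper on 19 of them, 17 of which had fallen with cerium in copper-free medium. It acted more negatively with copper on 58, of which 37 fell with cerium in copper-grown cells and 19 rose with it in copper-free medium. ADVE02_v2_10208 had the smallest p, with a difference of 4.70 (SE 0.31, adjusted p 2.31e-47). In the authors' deposited tables it changed by -2.79 with cerium without copper (SE 0.22, adjusted p 3.59e-33) and by 1.91 with copper (SE 0.22, adjusted p 2.9e-15). It was the feature called in opposite directions. For ADVE02_v2_12108 the difference was 5.58 (SE 0.45, adjusted p 1.80e-31), and all 13 features of its run passed the test, with a median difference of 5.07. On the negative side, ADVE02_v2_12128 had a difference of -3.49 (SE 0.32, adjusted p 1.47e-24). Copper changed it by 4.18 without cerium (SE 0.23) and by 0.69 with cerium (SE 0.23, adjusted p 0.00535) in the authors' deposited tables. ADVE02_v2_30013 had a difference of -3.90 (SE 0.46, adjusted p 2.57e-14). In the run of 3 that rose with cerium in both media, no difference passed the z test, 0 of the 3 had an unadjusted p below 0.05, and the median difference was 0.19. The same z test passed no feature of the run of 10 or of the run of 13 that fell with copper, with 1 and 0 at an unadjusted p below 0.05.

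**Figure D3:**
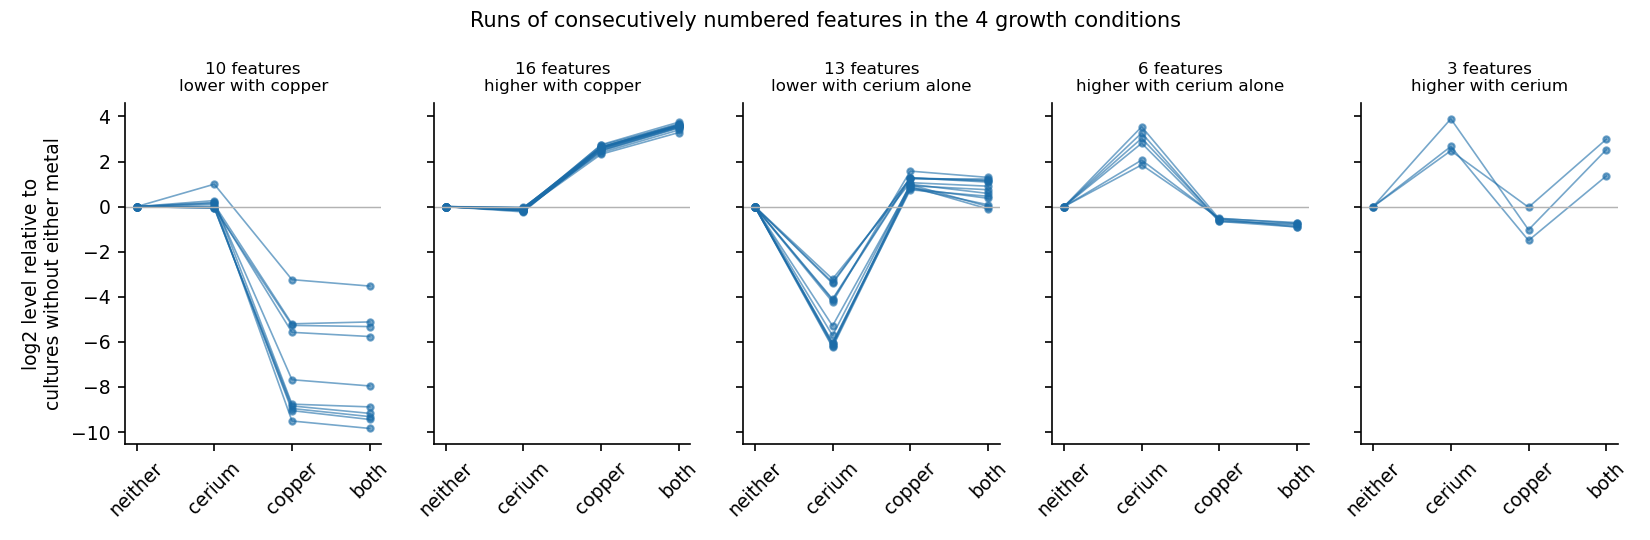
Log2 level of each feature of 5 runs of consecutively numbered features, relative to cultures without either metal, in cultures with neither metal, cerium, copper or both; each line is 1 feature and the values are the authors' fold changes. The run of 10 fell with copper with or without cerium, the run of 13 fell with cerium alone with a median of -5.29, and the run of 3 rose with cerium in both media.

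Copper and cerium together were set against neither metal, and copper alone against cerium alone. With both metals, 1361 features were higher and 1385 lower than with neither in the authors' deposited table. ADVE02_v2_12510 (-9.84, SE 0.23) and ADVE02_v2_12513 (-9.44, SE 0.33) were again lowest, and ADVE02_v2_12041 (5.45, SE 0.26) and ADVE02_v2_11126 (3.77, SE 0.67, adjusted p 4.85e-07) highest in the authors' deposited table. Copper alone gave 932 features higher and 622 lower than cerium alone in the authors' deposited table. Its lowest features were ADVE02_v2_12510 (-9.67, SE 0.23) and ADVE02_v2_12514 (-9.03, SE 0.22) in the authors' deposited table. Its highest, ADVE02_v2_12109 (7.16, SE 0.44, adjusted p 1.00e-56) and ADVE02_v2_12106 (7.06, SE 0.40, adjusted p 9.64e-68) in the authors' deposited table, are among the 13 that fell with cerium alone. These comparisons share libraries with those above and add no independent evidence. With an absolute log2 fold change of at least 1 the counts were 1537 and 868, and at an adjusted p below 0.01 the comparison of the single metals gave 801. With the median feature shifted to 0, that comparison gave 796 features higher and 772 lower.

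Structural RNA, the tRNA and rRNA features read from their identifiers, was the one list fixed beforehand that could be matched. With copper, 1 of its members rose and 4 fell without cerium, and 8 rose and 7 fell with cerium, all of them tRNAs, in the authors' deposited tables. Adjusted over the list alone, 1 rose and 2 fell without cerium, and 2 rose and 4 fell with it. With cerium, no member was called in either medium by the authors' DESeq2 adjusted p or adjusted over the list alone, while 3 members without copper and 5 with copper had an unadjusted p below 0.05. The median log2 fold change of the list was -0.33 for copper without cerium, -0.10 for copper with cerium, -0.05 for cerium without copper and 0.22 for cerium with copper. None passed limma's cameraPR test against all other features (adjusted p 0.103, 0.762, 0.745 and 0.103). Against 10000 random lists of like abundance, the first and the last stood apart (adjusted p 0.0016 and 0.0256). Those lists were drawn feature by feature, so these p-values ignore any correlation between members and can be too small. For cerium with copper, rRNA and tRNA had medians of opposite sign, with -0.75 for the 6 rRNA features and 0.25 for the 49 tested tRNAs. In the authors' deposited table the copies of 16S and 23S rRNA had values between -0.81 and -0.75, and those of 5S rRNA 0.056 and 0.073. Adjusted over rRNA alone, 4 of the 6 were lower for cerium with copper, and adjusted over tRNA alone, 1 tRNA was higher for cerium without copper. Both divisions were made after the data were seen. The 15 misc_RNA features, kept apart from the list, gave 3 rises and 5 falls for copper with cerium, 1 fall for copper without cerium and 2 falls for cerium with copper in the authors' deposited tables. Each rRNA has a pair of near-identical copies that can share reads, so their values are uncertain and not independent. The RNA was also depleted of rRNA before sequencing. The rRNA counts are what depletion left, and a difference in depletion between conditions was not tested and cannot be told apart from a change in rRNA.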

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

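The test of the difference was planned, and the tests of technical explanations in this part were chosen after the results were seen. Cerium effects differed with and without copper for 77 features. Among single features, the cerium effect with copper minus that without was 4.70 (SE 0.31) for ADVE02_v2_10208, 5.58 (SE 0.45) for ADVE02_v2_12108, -3.49 (SE 0.32) for ADVE02_v2_12128 and -3.90 (SE 0.46) for ADVE02_v2_30013. For the most abundant feature, ADVE02_v2_11076, it was -4.44 (SE 0.83, adjusted p 1.88e-05). As a median over a run of consecutively numbered features, it was 5.07 for the run of 13 that fell with cerium alone. The medians were -3.10 and -2.48 for a run of 6 and a run of 5 with numbers starting with 3, which rose with cerium alone. Chance splits of the libraries and outlying libraries were not analysed here, since the tables hold no values per library.

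The first pattern is that copper was called for 2967 features with cerium and for 826 without it. The deposited standard errors were alike with and without cerium, with a ratio of medians of 0.993, so they do not account for the extra calls. A fit of all 12 libraries gives near-equal standard errors by design, so this ratio says nothing of the spread between libraries. A library mix-up, in which 1 of the 3 libraries with copper alone held RNA of a culture without copper, would keep every log2 fold change without cerium above about -1.58. The 30 features that fell by 4 or more with cerium had a median of -5.28 without it, well past that limit. A change of the copper response by cerium stays open. Of 2225 features called for copper only with cerium, 54 passed the test of the difference. In simulation that test recovered 30% of differences of 1 on the log2 scale, a share that need not carry over to the data.

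The second pattern is the run of 13 that fell with cerium only in copper-free medium, where the difference itself passed the test for each member. A fall carried by 1 or 2 of the 3 libraries with cerium alone would give no log2 fold change below about -1.58, and the median of the run was -5.29. A difference in centring between the comparisons would move all features the same way by the same amount, but of the 4872 other features tested 1 (0.0205%) had a positive difference as large as the lowest of the run, 3.06. An effect of cerium that differs with copper remains as a hypothesis.

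The third pattern is that 90.5% of the features called for cerium in copper-grown cells fell. The authors' filtering of low counts was argued against as the whole cause, since 90.0% fell with all features adjusted together. Centring was not decided, since the share was 88.4% with the median feature at 0 but the shift was only 0.015. Libraries with copper alone that stood above those with neither metal would raise the features that fell. Against neither metal, these 364 features had a median log2 fold change of -0.066 with copper alone, with 8 called lower and 32 higher. That argues against this explanation for the features as a set, though not for the 32. Libraries with copper alone that stood apart in other ways stay open. Of the 364 features, 300 also fell with both metals against neither. Both comparisons share the libraries with both metals, so libraries of that condition that stood apart would give the same falls. An effect of cerium in copper-grown cells stays open as well and was not tested apart from these.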

How the results depend on the processing

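The alternatives without RNA features, without identifiers numbered from 3, with 1 copy of each rRNA, and with tRNA and rRNA alone were chosen after the data were seen. Of 126 values under alternatives, 107 kept their direction and side of the threshold or stayed within 1.5 times the main count. These include 48 values of the 24 printed pairs, the first 2 features in each direction of each comparison, under adjustment over all features and under centring. Those features have the largest changes, and centring moved no fold change by more than 0.062. The 48 values could therefore not turn and are no evidence of robustness. Other values were fixed too. The difference of the copper effects equals that of the cerium effects and gave the same 77 features. Adjustment over all features changed no count where no adjusted p was blank (2967, 52, 2746 and 1554 calls). A count could also stay within 1.5 times while its balance turned. For copper without cerium, it went from 469 higher and 357 lower to 394 and 407 with the median feature shifted to 0. At an adjusted p below 0.01, 376 features were called for copper without cerium, 183 for cerium with copper, 801 for copper alone against cerium alone and 50 for the difference. The copper overlap then held 145 features that rose and 167 that fell, and the cerium overlap 0 that fell. With an absolute log2 fold change of at least 1, the calls were 481 for copper without cerium, 1750 for copper with cerium, 260 for cerium with copper, 1537 for both metals against neither and 868 for copper alone against cerium alone. The overlaps were 255 and 153 for copper and 0 for falls with cerium. These counts are smaller because the criterion is stricter. Without identifiers numbered from 3, cerium without copper gave 29 calls, as 21 of its rises lie in that series and 2 falls passed the threshold no longer once p-values were adjusted over the other features. The structural RNA list, with medians of -0.33 for copper without cerium and 0.22 for cerium with copper, passed against random lists and not with cameraPR. Random lists ignore any correlation between members, while cameraPR allows for a preset one. At a preset correlation of 0.1, cameraPR gave an adjusted p of 0.677 for both. The cause was not tested. For cerium with copper, rRNA alone turned the median to -0.75 (adjusted p 0.212), since the medians of rRNA and tRNA had opposite signs. No paired analysis was possible because the tables hold no values per library. For the same reason other count models and filters, other pseudocounts, leaving out a library and an estimated correlation were not run. The unknown depth per library limits what can be said of features with low counts.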

Other observations

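The tests in this part were chosen after the results were seen. Features whose identifier number starts with 3 held most of the rises with cerium in copper-free medium. Of the 152 features in this series, 21 rose with cerium in copper-free medium, of 31 numbered features that rose in all (odds ratio 74.6, Fisher's exact adjusted p 6.12e-24 over 24 such tests). With cerium in both media, 92 of the 152 fell with copper and 11 rose. Both counts rest on the same libraries with cerium alone. Without cerium, 6 fell with copper and 1 rose. What the leading digit stands for is not given in the sources used here. Features of a series are not independent, so the p-value is too small.

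Called features stood next to each other in number more often than in 10000 shuffles of the calls among the numbered features. For copper without cerium, 314 calls stood in runs of at least 3 consecutive numbers of 1 direction, against at most 55 in the shuffles. The counts were 1814 against at most 794 for copper with cerium, 44 against at most 3 for cerium without copper, and 136 against at most 28 for cerium with copper. Each p was 0.0001, the smallest that the shuffles can give. Whether consecutive numbers are neighbours on the genome, or transcribed together, was not tested.

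Copper fold changes were larger with cerium than without, with a ratio of 1.78 between the median absolute log2 values. A candidate explanation is that cells with both metals stood further along the copper response than cells with copper alone. Of the 826 features called for copper without cerium, 570 (69.0%) had a cerium effect in copper-grown cells of the same sign as the copper effect. With no effect, the shared libraries with copper alone would push this share below 50%, so the excess lies against that bias, but it stays under the 75% set for the test and leaves the explanation open. The share was 73.3% among features that rose with copper and 63.3% among those that fell.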
